A study of Danio rerio with 24 samples.

How the data were processed

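Gene expression was measured in caudal fins of zebrafish (Danio rerio) with 24 single-colour Affymetrix zebrafish genome arrays. Per the labels, the arrays fall into 8 groups of 3, made from control or diabetic fish with fins taken at 0, 12, 24 or 48 h after amputation. Diabetes was induced with streptozotocin, a toxin of pancreatic beta cells, at 350 mg/kg in 5 injections, the first on day 1 and the last on day 19, per the labels' protocols. The protocol describes citrate buffer injections for the control fish, whereas the series' design text calls them untreated. RNA came from triplicate samples of 15 fins at each time, and whether each sample held 15 fins is not given in the sources used here. cRNA was labelled with biotin from 6 ug of RNA, per the labels' protocols. No source says whether replicates came from separate fish or cultures, so p-values measure the spread between these samples, which can be partly technical.

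The deposited values are on a log2 scale, 1 per probe set and array. They were made with GCRMA and Partek, per the submitters' processing notes, and the versions of both are not given in the sources used here. GCRMA corrects background with a model of probe sequence, normalizes between arrays and summarises the probes of a probe set; which of these steps were run, and with what settings, is not stated. The log base was taken from the range of the deposited log2 values, 0.90 to 15.01. Array medians ran from 3.85 to 3.95, so the arrays had already been brought near a common scale. The medians did not overlap between treatments, at 3.85 to 3.88 on control and 3.89 to 3.95 on diabetic arrays. Median centring, an alternative below, lowers diabetic minus control values by such offsets. The number of arrays, 3 per group, limits the precision. Scanner files and genome positions were not used here.

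The table held 15617 probe sets, of which 115 AFFX control probe sets were left out of the tests and 15502 were tested. Gene names came from the platform annotation, updated through Entrez gene numbers. Exactly 1 symbol was given for 10795 probe sets, several for 135 and none for 4572. Probe sets with several symbols or none were tested and are not named. For gene lists, each gene was represented by its probe set with the highest mean over all arrays, which gave 8793 genes. Probe sets of close paralogs, such as ptgdsb.1 and ptgdsb.2, can cross-hybridize, and this was not tested.

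Differences were fitted with limma (version 3.58.1 under R 4.3.3) as group means over all 24 arrays, so that the groups share 1 estimate of the spread, followed by eBayes. The adjusted p is limma's p after Benjamini-Hochberg adjustment over the 15502 probe sets of a comparison, and a probe set passed at an adjusted p under 0.05. There were 14 comparisons. These were diabetic minus control at each of 4 times and on average over them, the later times minus 0 h within each kind of fish, and the difference between those responses at 12, 24 and 48 h. Each difference is given in log2 units with its standard error (SE), and groups are given as mean and SD with n = 3.

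Before the data were examined, 34 lists of genes for regeneration, matrix, proliferation, stress, metabolism, signalling and cell types were fixed, as were the rule for named genes, the tests and most of the alternatives. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry. Counts of list members come from the fit over the 8793 genes, beside counts adjusted over the list alone. The named genes are the 10 largest rises and 10 largest falls for diabetic minus control. For responses to amputation they are the 8 and 8 largest, and for differences between responses the 6 and 6 largest. They had to pass the test, have a gene symbol that is not a clone or locus name, be 1 probe set per gene and, except for differences between responses, have groups that do not overlap (for the average, 1 sign at all 4 times). Up to 4 list members with the smallest adjusted p and 17 landmark genes of regeneration and diabetes, 13 of them measured, were also named. The ranking was followed from the top where space was short.

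The script was tested on simulated data for diabetic minus control at 0 h with 15502 probe sets. Of 50 probe sets changed by 0.5 log2 units it recovered 42.0%, of 50 changed by 1 unit 64.0%, and of those changed by 2 or 3 units 100.0%. There were 14 false calls among 167. In a second simulation with 8793 genes, all members of 1 list of 34 were shifted by 1 log2 unit, and camera called that list and 0 others. Both simulations drew genes independently, so they do not test the preset correlation between genes.

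Alternatives were an intensity trend with a robust prior, leaving out the dimmest probe sets, cyclic loess, median centring, array weights, only the groups compared, the replicate number as a block, 1 probe set per gene and leaving out each array in turn. Leaving out control 24 h replicate 3 from comparisons that do not use it was chosen after seeing the data. The labels give no hybridization date or batch. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.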

Results

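Fins of control fish and of fish made diabetic with streptozotocin were compared before and during early regeneration. The zebrafish caudal fin regrows after amputation through a wound epidermis, then a blastema of proliferating cells, then new bone and actinotrichia, the collagen-rich fibrils at the fin edge. Each of the 8 labelled groups held 3 arrays. Because at least 1 array, control 24 h replicate 3, did not group by its label, control and diabetic below mean the arrays labelled so. Every control sample title also carries a (D) that no source explains, so what a diabetic minus control value compares rests on labels that are not fully understood.

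Correlations between arrays ran from 0.888 to 0.994, and 20 of 24 arrays correlated best with their own group. Control 24 h replicate 3 had a mean correlation of 0.992 with the control 12 h arrays and 0.916 with the other arrays of its own group. Replicates 1 and 2 of that group had mean correlations of 0.981 each with the control 48 h arrays, against 0.951 and 0.952 with their own group. Their own-group means include replicate 3, so these values do not show that replicates 1 and 2 stood apart from each other. The first principal component held 55.2% of the variance. Means of the dimmest probe sets went up to 3.19, and signal above background was not shown for a group mean in that range. Where 1 group lay there, the size of a difference is uncertain. Of 28 pairs of groups, the 4 with the highest median correlation were diabetic 24 h with 48 h (0.986), diabetic 0 h with 12 h (0.986), control 0 h with 12 h (0.983) and control 24 h with 48 h (0.980). At 0 h, poly-A spike-ins, which are added before labelling, differed by -0.89 log2 units, diabetic minus control (6.26 ± 0.32 against 7.15 ± 0.38, SD, n = 3; two-sided exact permutation p = 0.10, the smallest that 3 against 3 allows). The 3' minus 5' difference of the GAPDH control probe sets, a measure of RNA integrity, was 1.69 ± 0.13 and 1.42 ± 0.18 in these groups (n = 3; two-sided exact permutation p = 0.10).

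**Figure D1:**
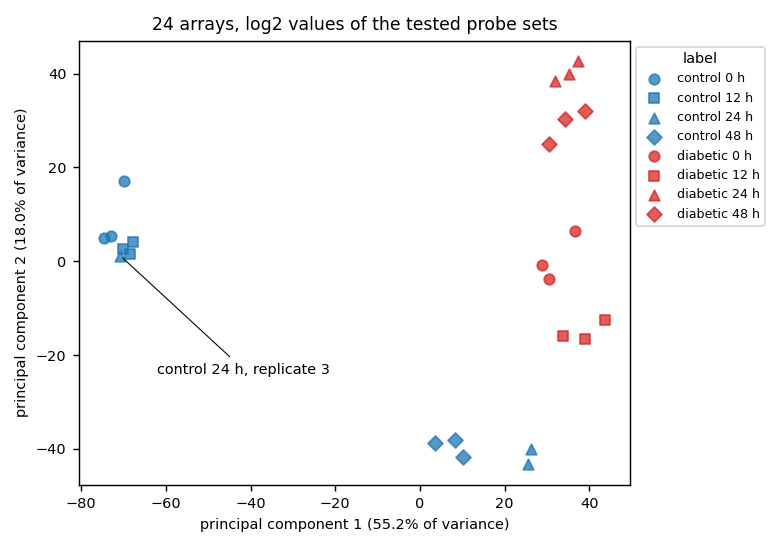
Scores of the 24 arrays on the first (x axis, 55.2% of variance) and the second (y axis) principal component of the log2 values, coloured by the treatment label and shaped by the time label. The array labelled control 24 h replicate 3 lies at -70.8 on the first component, beside the control 0 h and 12 h arrays, whereas replicates 1 and 2 of its group lie at 26.3 and 25.6.

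Diabetic and control fins were first compared at 0 h, the labelled time of amputation. Serpinh1b, the collagen chaperone Hsp47, was 7.36 ± 0.81 log2 units (SE) higher on the diabetic arrays, at 11.91 ± 0.56 against 4.54 ± 0.43 (SD, n = 3; limma adjusted p = 7.87e-06). Also higher were tph1b, a tryptophan hydroxylase of serotonin synthesis (6.35), hsp90aa1.2, a cytosolic heat shock protein (6.03), and tncb, a tenascin C of the wound matrix (5.82). Keratins krt94 (5.62) and krt18a.1 (5.43), the tubulin tubb5 (5.34), the activin subunit gene inhbaa (5.26), jac4 (5.73) and ntrnl2 (5.32) were higher too. Lower were the prostaglandin D2 synthase paralogs ptgdsb.2 (-6.98 ± 0.79) and ptgdsb.1 (-5.11), the chromatin protein gene hmgb3a (-6.22), the Fgf-binding protein gene fgfbp2a (-5.83) and the chemokine gene cxcl12a (-5.16). So were the retinol carrier rbp4 (-4.66), the mucin muc5.1 (-4.53) and rgs2 (-4.32). Linc.pou2af1 (-5.36) and bhlhe41 (-4.27) followed. The control means of tph1b, hsp90aa1.2, tncb, ntrnl2 and inhbaa and the diabetic means of hmgb3a and cxcl12a lay in the range of the dimmest probe sets.

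Among landmark genes at 0 h, the retinoic acid synthesis gene aldh1a2 (3.68), the fibronectin gene fn1b (3.67), the replication clamp pcna (3.13), junba (2.96), lef1 (2.93), mmp13a (2.80), wnt5b (2.28) and msx1b (1.26) were higher on the diabetic arrays and passed. Aldh1a2 (2.62 to 2.77) and wnt5b (2.32 to 2.56) lay in the range of the dimmest probe sets on the control 0 h arrays, so the size of these 2 differences is uncertain. Mmp9 also passed (0.96, adjusted p = 0.0424), and did not after cyclic loess, after median centring, with the replicate block, without control replicates 1 (0.93), 2 (1.00) and 3 (0.94) or without diabetic replicates 2 (1.04) and 3 (0.69). Mmp13a did not pass without diabetic 0 h replicate 3 (2.46). The gluconeogenesis gene pck1 (-0.49) and top2a (0.00) did not pass, nor did igfbp1a (1.53) except without control 24 h replicate 3, or wnt10a (0.15) except with an intensity trend and without diabetic 0 h replicate 2 (0.19). On the 0 h arrays top2a (2.95 to 3.01) and wnt10a (2.35 to 2.65) lay in the range of the dimmest probe sets, so signal above background was not shown for them.

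Of 57 measured fin regeneration markers, 22 were higher and 7 lower at 0 h, among them lamb1a (2.98), and the same numbers held adjusted over the list alone. The list was called higher by camera (adjusted p = 0.00435), but not with an estimated correlation (adjusted p = 0.177 with an estimated correlation). Of 28 endoplasmic reticulum stress genes 23 were higher and 3 lower, in all genes and adjusted over the list alone, with calr3b (2.50), hspa5 (2.50) and hsp90b1 (3.56) as examples (adjusted p = 0.396 with an estimated correlation). Heat shock proteins and chaperones had 25 higher and 2 lower of 39, or 25 and 3 adjusted over the list alone (adjusted p = 0.445 with an estimated correlation). In DNA replication and S phase, 29 of 38 genes were higher and 0 lower, or 29 and 1 adjusted over the list alone, including dut (2.93) and rpa3 (2.51, with a control mean of 3.03 that is as low as the dimmest probe sets), with adjusted p = 0.445 with an estimated correlation. Mitochondrial oxidative phosphorylation had 45 higher and 4 lower of 68, or 47 and 4 adjusted over the list alone, such as ndufv2 (1.81) and uqcrfs1 (1.62), and its adjusted p was 0.445 with an estimated correlation. Of 73 ribosomal protein genes 13 were higher and 33 lower, or 17 and 35 adjusted over the list alone, and the list was called lower (adjusted p = 0.468 with an estimated correlation). The lymphocyte list was called lower, with 0 higher and 5 lower of 10, also adjusted over the list alone (cd28 -1.19, gata3 -1.68, ikzf1 -1.66), with adjusted p = 0.445 with an estimated correlation, and this call ended after cyclic loess. Polr1g, which encodes an RNA polymerase I subunit, was 1 of the 5. Without it 4 of 9 were lower (camera adjusted p = 0.0187, or 0.445 with an estimated correlation). Inflammatory cytokines and NF-kB targets were not called (5 higher and 2 lower of 17, median 0.26, camera adjusted p = 0.374).

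In total 5159 of 15502 probe sets passed at 0 h, 2701 higher and 2458 lower on the diabetic arrays, and 2786 of them differed at least 2-fold. Which direction had more calls depended on scaling, with 2385 higher and 2649 lower after cyclic loess and 2530 and 2722 after median centring. Of the 34 lists, camera called 12 higher and 3 lower, and 0 of these calls held with an estimated correlation.

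At 12 h the diabetic arrays differed from the control arrays in much the same way as at 0 h. Jac4 (7.03 ± 1.00, SE), ntrnl2 (6.80), serpinh1b (6.79), tubb5 (5.90), tph1b (5.71), krt94 (5.69), tuba1b (5.31), the growth factor gene mdka (5.27), krt18a.1 (5.23) and inhbaa (5.11) were highest. Fgfbp2a (-6.71 ± 1.05), ptgdsb.2 (-6.36), hmgb3a (-6.27), cxcl12a (-5.91), linc.pou2af1 (-5.86), cyp8b1.3 (-4.93), the urea transporter gene slc14a2 (-4.56), rgs2 (-4.52) and the glycine decarboxylase gene gldc (-4.22) were lower. The collagenase gene mmp13a (4.74), junba (2.85), mmp9 and igfbp1a (3.06) were higher, and pck1 was lower (-1.30, adjusted p = 0.00471). Pck1 did not pass when only the compared groups were fitted, and its diabetic levels of 2.75 to 2.87 and control replicate 2 (3.02, against 4.62 and 4.67) were as low as the dimmest probe sets, so a fall was not shown. The control means of ntrnl2, tubb5 and tph1b and the diabetic means of hmgb3a, cxcl12a, linc.pou2af1, slc14a2 and rgs2 also lay in that range. Across probe sets, which are not independent replicates, the differences at 0 h and at 12 h had a Pearson r of 0.91, with no array in common. Probe sets higher at both times numbered 2129, where 531.8 would be shared by independent lists, and 1849 were lower at both against 465.7.

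Extracellular matrix remodelling genes were higher at 12 h (18 of 28, 2 lower; 18 and 3 adjusted over the list alone), with loxl2b (2.77) and postnb (2.11), and adjusted p = 0.41 with an estimated correlation. Endoplasmic reticulum stress genes had 21 higher and 3 lower of 28, also adjusted over the list alone, with pdia3 (1.54) and hspa5 (1.91), and adjusted p = 0.42 with an estimated correlation. In hypoxia and glycolysis 21 of 45 were higher and 4 lower, or 21 and 5 adjusted over the list alone, among them ndrg1a (2.54) and pkma (2.44), with adjusted p = 0.42 with an estimated correlation. Complement and acute phase genes were called lower, with 1 higher and 8 lower of 27, or 1 and 7 adjusted over the list alone (cfd -4.06, c4b -3.53, c4 -2.05), with adjusted p = 0.518 with an estimated correlation, and the call ended after cyclic loess. At 12 h 5989 probe sets passed, 3052 higher and 2937 lower. The share of higher calls, 51.0%, was 49.6% after cyclic loess (2865 higher, 2907 lower), 41.7% after median centring (2834 higher, 3956 lower) and also under 50% with array weights (3681 higher, 4775 lower). Poly-A spike-ins differed by -0.15 log2 units at 12 h (two-sided exact permutation p = 0.40, n = 3), and the GAPDH 3' minus 5' difference by -0.02 (exact p = 0.90). Camera called 9 lists higher and 3 lower, and 0 held with an estimated correlation.

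**Figure D2:**
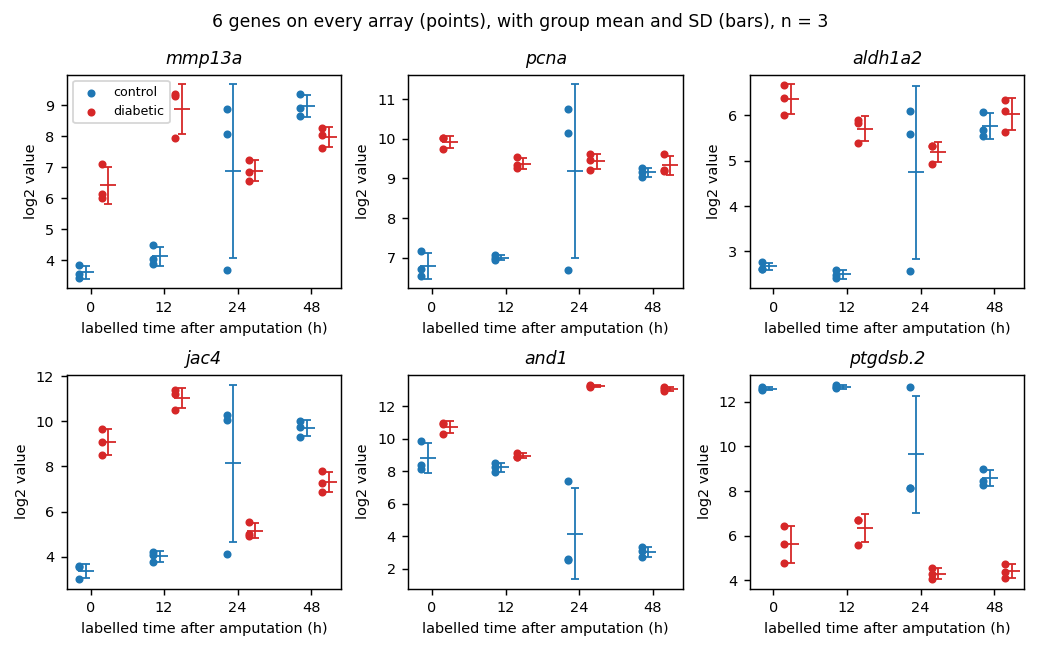
Log2 value (y axis) of 6 genes on each array (points) against the labelled time in hours (x axis), with the group mean and SD as bars (n = 3) for control (blue) and diabetic (red) arrays. In each gene 1 control 24 h array, replicate 3, lies apart from replicates 1 and 2, as for mmp13a at 3.69 against 8.07 and 8.89.

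At 24 h the largest differences were those of and2 and and1. These genes, which encode actinodins, proteins of the actinotrichia, were 9.16 ± 0.44 and 9.08 ± 0.82 log2 units (SE) higher on the diabetic arrays, and and2 was at 12.21 ± 0.10 against 3.05 ± 0.41 (SD, n = 3). The control 24 h means of and2, enam, pcp4a and ifitm5 and the diabetic mean of kif20a were as low as the dimmest probe sets (up to 3.19), as was and1 on control replicates 1 and 2 (2.59 and 2.54), so signal above background was not shown there and the size of these differences is uncertain. Enam (8.60), pcp4a (7.49), the type X collagen gene col10a1a (7.26), the bone gene ifitm5 (6.86), hsd17b8 (6.36), serpinh1b (5.66), ecrg4a (5.40) and c1qtnf5 (5.27) followed. Prg4a, the lubricin gene (-6.26), ptgdsb.2 (-5.35), the mucin muc5.2 (-5.32), the mitotic kinesin gene kif20a (-4.13), ptgdsb.1 (-3.79), the complement gene cfd (-3.65), fkbp5 (-3.41), tcnbb (-3.34), nrg1 (-2.99) and klf9 (-2.98) were lower. The mean of the mitosis list differed from kif20a in direction, at 5.22 ± 0.05 on diabetic 24 h and 4.76 ± 0.20 on control 24 h arrays (SD, n = 3). Fkbp5 and klf9, which respond to glucocorticoids, did not pass without diabetic 24 h replicate 1 (-2.12 and -2.21) or with array weights, and klf9 also not without control 24 h replicate 3 (-2.21). Without control 24 h replicate 3, ptgdsb.2 was at -3.84, ptgdsb.1 at -2.55, cfd at -2.87, serpinh1b at 4.34, muc5.2 at -5.73 and and1 at 10.69. When only the compared groups were fitted, serpinh1b, ptgdsb.2, ptgdsb.1, cfd, fkbp5, nrg1, klf9, wnt5b and lef1 did not pass.

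The landmark genes msx1b (2.86), lef1 (2.64) and wnt5b (1.75) were higher on the diabetic 24 h arrays and passed. Pcna (0.24 ± 0.62), mmp13a (0.00 ± 0.84) and aldh1a2 (0.44 ± 0.56) did not pass. Their levels on control 24 h replicate 3 were far below those on replicates 1 and 2 (6.69 against 10.74 and 10.14 for pcna, and 2.57 against 5.58 and 6.10 for aldh1a2). Without that array pcna (-1.01), mmp13a (-1.60), aldh1a2 (-0.65) and mmp9 (-0.74) were lower on the diabetic arrays and passed.

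Fin regeneration markers were higher on the diabetic arrays at 24 h (32 of 57, 2 lower; 34 and 3 adjusted over the list alone; camera adjusted p = 6.21e-15), including sema3d (2.11) and lamb1a (3.95). Fibrillar collagen and bone matrix genes had 12 higher and 1 lower of 19, or 14 and 3 adjusted over the list alone (camera adjusted p = 1.57e-11), among them sparc (3.77), the osteoblast regulator runx2a (3.98) and col11a1a (4.61). In extracellular matrix remodelling 16 of 28 were higher and 1 lower, or 16 and 4 adjusted over the list alone. Among fibroblast and connective tissue markers, 16 of 29 were higher and 2 lower, or 18 and 3 adjusted over the list alone, with dcn at 3.05. The signalling list of Fgf, Bmp, activin, hedgehog and retinoic acid genes had 21 higher and 4 lower of 62, or 25 and 5 adjusted over the list alone (etv5b 1.71, bmp4 2.35). These 5 lists were the ones whose calls held with an estimated correlation, with adjusted p = 1.21e-05, 0.000275, 0.00102, 0.000971 and 0.0171 in that order.

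Neutrophil markers were called lower at 24 h, with 0 higher and 5 lower of 15, or 0 and 8 adjusted over the list alone (cebp1 -1.18, nccrp1 -1.23; adjusted p = 0.123 with an estimated correlation). Epidermis and keratin markers had 4 higher and 16 lower of 50, or 4 and 18 adjusted over the list alone (spint1a -1.16, agr2 -2.68; adjusted p = 0.472 with an estimated correlation), and the call ended after median centring and without control 24 h replicate 2. Ribosome biogenesis genes had 0 higher and 16 lower of 46, or 0 and 24 adjusted over the list alone (ddx21 -1.67, pes -1.13; adjusted p = 0.467 with an estimated correlation). Wnt signalling was called higher with 10 higher and 1 lower of 32, also adjusted over the list alone (fzd7a 1.71), although its median was -0.02 and its mean 0.43, and adjusted p = 0.143 with an estimated correlation.

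At 24 h 3777 probe sets passed, 1609 higher and 2168 lower. Among those that differed at least 2-fold, 821 were higher and 332 lower. The share of higher calls, 42.6%, was 58.9% after cyclic loess (1629 higher, 1139 lower) and 25.6% after median centring (1584 higher, 4614 lower), and the median over all probe sets was -0.10. At 24 h hybridization spike-ins differed by -0.44 log2 units (two-sided exact permutation p = 0.10, the smallest possible, n = 3) and poly-A spike-ins by -0.91 (exact p = 0.30). Without control 24 h replicate 3, 3896 passed, 1805 higher and 2091 lower, of which 2570 were among the 3777. The count was 2088 without diabetic 24 h replicate 1, 2258 without replicate 2, and 832 when only the compared groups were fitted (623 higher, 209 lower). Without the dimmest probe sets 1471 were higher and 1154 lower.

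At 48 h and1 was 10.01 ± 0.82 log2 units (SE) higher on the diabetic arrays (13.08 ± 0.12 against 3.06 ± 0.30, SD, n = 3; limma adjusted p = 1.43e-07), and and2 was 8.71 ± 0.44 higher. Enam (8.24), col10a1a (7.65), pcp4a (6.97), ifitm5 (5.76), the homeobox genes dlx5a (5.63) and dlx2a (5.47), col10a1b (5.51) and egfl6 (5.49) were higher. Muc5.2 (-5.30), prg4a (-5.17), cfd (-4.50), ptgdsb.2 (-4.18), nrg1 (-3.42), ptgdsb.1 (-3.15), rasgrp4 (-3.07), fkbp5 (-3.03), agr2 (-2.99) and arhgap32a (-2.98) were lower. The control means of and1, enam, pcp4a and ifitm5 and the diabetic mean of arhgap32a lay in the range of the dimmest probe sets. Fkbp5 did not pass after cyclic loess, with only the compared groups, without control 48 h replicates 1 (-3.02), 2 (-3.06) and 3 (-3.0) or without diabetic 48 h replicates 1 (-3.14) and 2 (-1.72). Msx1b (2.51), lef1 (1.84) and wnt5b (1.44) were again higher, whereas mmp13a (-0.98), pcna (0.18), fn1b (-0.42) and junba (-0.15) did not pass. Between 24 h and 48 h the differences had a Pearson r of 0.82 across probe sets, with no array in common, and 882 probe sets were higher at both times (136.5 for independent lists). Between 0 h and 48 h r was 0.27.

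Fibrillar collagen and bone matrix genes had 14 higher and 0 lower of 19 at 48 h, also adjusted over the list alone, including sparc (3.80), col11a1a (4.38) and msx2b (5.14), and adjusted p = 0.000424 with an estimated correlation. Fin regeneration markers had 30 higher and 1 lower of 57, or 32 and 2 adjusted over the list alone (adjusted p = 4e-05 with an estimated correlation). Extracellular matrix remodelling had 13 higher and 2 lower of 28, or 14 and 2 adjusted over the list alone, and fibroblast and connective tissue markers 13 higher and 4 lower of 29, also adjusted over the list alone (adjusted p = 0.0256 with an estimated correlation for each). Neutrophil markers were lower (0 higher, 5 lower of 15; 0 and 7 adjusted over the list alone; cebpa -2.08, nccrp1 -1.61), with adjusted p = 0.0445 with an estimated correlation. Ribosome biogenesis genes had 0 higher and 26 lower of 46, or 0 and 29 adjusted over the list alone (ncl -1.49, rrp1 -1.28, utp4 -1.33; adjusted p = 0.216 with an estimated correlation). Epidermis and keratin markers had 2 higher and 19 lower of 50, or 2 and 20 adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). In total 2442 probe sets passed, 1315 higher and 1127 lower. The share of higher calls, 53.8%, was 42.7% after median centring (1235 higher, 1654 lower), and 4158 passed with array weights (2028 higher, 2130 lower). At 48 h poly-A spike-ins were at 7.23 ± 0.33 on the diabetic and 7.94 ± 0.13 on the control arrays (SD, n = 3; difference -0.71, two-sided exact permutation p = 0.10, the smallest possible).

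**Figure D3:**
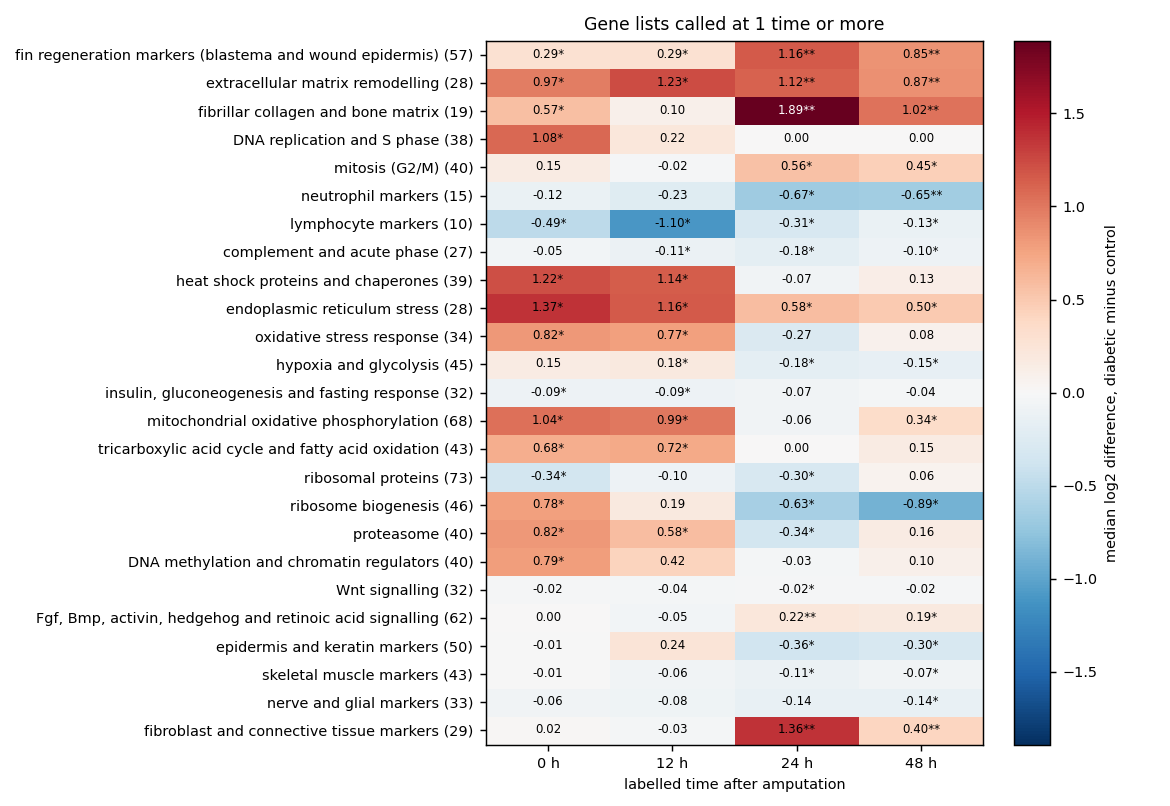
Median log2 difference, diabetic minus control (colour and printed value), of the gene lists (rows, with the number of measured genes) that camera called at 1 labelled time or more (columns, in hours). A single asterisk marks a call with the preset correlation and a double one a call that held with an estimated correlation, such as fibrillar collagen and bone matrix at 24 h (1.89).

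On average over the 4 times, serpinh1b (6.31 ± 0.41, SE), enam (5.83), and1 (5.43), and2 (4.76), tncb (4.53), pcp4a (4.38), tph1b (4.37), rcn3 (4.33), egfl6 (4.26) and c1qtnf5 were highest on the diabetic arrays. Ptgdsb.2 (-5.72 ± 0.39), prg4a (-4.69), hmgb3a (-4.14), ptgdsb.1 (-4.03), cfd (-3.84), muc5.2 (-3.72), fgfbp2a (-3.50), muc5.1 (-3.14), cyp8b1.3 (-3.13) and rgs2 (-3.08) were lowest. Landmark genes lef1 (2.43), wnt5b (2.02), aldh1a2 (1.90), fn1b (1.80) and msx1b (1.73) were higher, whereas for pck1 (-0.60, adjusted p = 0.00547) a fall was not shown, since all 4 diabetic means, the control 48 h mean and 7 of 12 control arrays were as low as the dimmest probe sets. In that range were also all 4 control means of enam, all 4 diabetic means of hmgb3a and some group means of and1, and2, tncb, pcp4a, tph1b, muc5.1, rgs2, wnt5b and aldh1a2. Igfbp1a (1.12) passed, and did not without control 0 h replicate 2 (1.05) or 3 (1.03), control 48 h replicate 3 (0.99), diabetic 0 h replicate 3 (1.08) or diabetic 24 h replicate 3 (1.06). Fin regeneration markers had 39 higher and 4 lower of 57, or 40 and 4 adjusted over the list alone, extracellular matrix remodelling 23 higher and 2 lower of 28, and fibrillar collagen and bone matrix 13 higher and 3 lower of 19, the last 2 lists with equal counts adjusted over the list alone. These calls held with adjusted p = 0.00035, 0.0105 and 0.0105 with an estimated correlation. The lymphocyte list (0 higher and 8 lower of 10, also adjusted over the list alone) was called lower, with gata3 at -1.52, and adjusted p = 0.276 with an estimated correlation. It held polr1g (-0.99), a gene of an RNA polymerase I subunit matched through an older symbol. Without polr1g 7 of 9 were lower (camera adjusted p = 0.00804, or 0.384 with an estimated correlation), and the list was not called at 24 h and 48 h (0.0891 and 0.0624). Of 15502 probe sets 9625 passed, 3680 higher and 5945 lower. Among those that differed at least 2-fold, 824 were higher and 555 lower. The share of higher calls, 38.2%, was 49.0% after cyclic loess (3724 higher, 3869 lower) and 29.5% after median centring (3348 higher, 8001 lower). Without the dimmest probe sets 3439 were higher and 3293 lower. At all 4 times 367 probe sets were higher and 172 lower.

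Within the control arrays, the response to amputation by 12 h was small. Kif20a (2.47 ± 0.28, SE), spon2b (1.60), the complement gene c4 (1.58) and scg3 (1.31) rose, and the globin gene hbaa1 (-3.05 ± 0.47), col10a1b (-2.29), hsd17b8 (-2.06) and cyp1a (-2.00, to a mean as low as the dimmest probe sets) fell. Scg3 did not pass without control 0 h replicates 1 (1.22) and 3 (1.09) or control 12 h replicates 1 (1.12) and 3 (1.32). Col10a1b did not pass without control 0 h replicates 1, 2 and 3 (-2.04, -2.31 and -2.51) or control 12 h replicates 1, 2 and 3 (-2.51, -2.30 and -2.06). When only these groups were fitted, scg3, col10a1b, hsd17b8 and cyp1a did not pass. None of the 13 measured landmark genes passed (pck1 did without control 12 h replicate 2, at 1.22, and lef1 without control 24 h replicate 3, at -0.86), with mmp13a at 0.52 ± 0.84, mmp9 at 0.11 ± 0.35, junba at 0.10 ± 0.49 and fn1b at 0.68 ± 0.57. Fibrillar collagen and bone matrix genes were called lower, with 0 higher and 3 lower of 19, or 0 and 5 adjusted over the list alone (runx2a -1.71, sparc -0.95, col1a1a -0.80), the 1 call of 10 that held with an estimated correlation (adjusted p = 0.0314). Immediate early and AP-1 genes were called lower with 0 higher and 2 lower of 32, also adjusted over the list alone (csrnp1a -1.17, gadd45ba -1.02; adjusted p = 0.581 with an estimated correlation), and the call ended without control 0 h replicate 1. In total 131 probe sets passed, 57 higher and 74 lower. The count was 67 without control 12 h replicate 2, 70 without replicate 3, 31 when only these groups were fitted and 430 without control 24 h replicate 3 (262 higher, 168 lower, so that the balance turned), whose spread enters the shared error.

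By 24 h jac4 (4.78 ± 1.00, SE), the heat shock gene hsp70.3 (4.29), tuba1b (3.74), kif20a (3.40), hsp90aa1.2 (3.36), psmb7 (3.25), krt94 and hspd1 (3.08) had risen on the control arrays. And1 (-4.65 ± 0.82), krt1-19e (-3.57), hbp1 (-3.21), slc16a12b (-3.10), muc5.1 (-3.09), jac1 (-2.94), col10a1b (-2.86) and col10a1a (-2.76) had fallen. Mmp13a (3.26), pcna (2.39), fn1b (2.18), aldh1a2 (2.08), junba (1.89), mmp9 (1.04) and wnt5b (0.81) passed. The control 0 h means of hsp90aa1.2, aldh1a2 and wnt5b lay in the range of the dimmest probe sets. Without replicate 1 or 2 of the control 24 h arrays none of these 7 passed, with mmp13a at 2.67 and 2.26, pcna at 1.62 and 1.92, fn1b at 1.62 and 1.61, aldh1a2 at 1.66 and 1.40, junba at 1.23 and 1.77, mmp9 at 0.88 and 0.63 and wnt5b at 0.58 and 0.64. Junba did not pass without control 0 h replicate 2 (1.63), nor did mmp9 and wnt5b without control 0 h replicate 1 (1.01 and 0.79), 2 (1.08 and 0.77) or 3 (1.03 and 0.89). Without control 24 h replicate 3 the values were 4.86 for mmp13a, 3.64 for pcna, 3.31 for fn1b, 3.17 for aldh1a2, 2.67 for junba, 1.61 for mmp9 and 1.22 for wnt5b. Without that array lef1 (1.24) and igfbp1a (2.61) passed too. Proteasome genes had 31 higher and 0 lower of 40, or 33 and 3 adjusted over the list alone (psmc2 1.13), and ribosome biogenesis genes 35 higher and 1 lower of 46, or 38 and 1 adjusted over the list alone (ddx18 1.70, wdr43 1.23), with adjusted p = 0.303 with an estimated correlation for each. Fibroblast and connective tissue markers had 4 higher and 11 lower of 29, or 4 and 14 adjusted over the list alone (tnn -2.33; adjusted p = 0.303 with an estimated correlation). The count of 3274 probe sets (1734 higher, 1540 lower) rests on single arrays: it was 5373 without control 24 h replicate 3, 1110 without replicate 1 and 1035 without replicate 2. When only these groups were fitted 2 passed, both lower, and none of the rises, falls and landmark genes named here did. After cyclic loess 1575 were higher and 1770 lower.

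By 48 h jac4 (6.33 ± 1.00, SE), ntrnl2 (5.67), inhbaa (5.48), krt18a.1 (5.37), mmp13a (5.35), tubb5 (4.95), tuba1b (4.94) and hsp70.3 (4.91) had risen on the control arrays. And1 (-5.76 ± 0.82), fgfbp2a (-5.30), hmgb3a (-4.94), col10a1b (-4.71), krt1-19e (-4.53), linc.pou2af1 (-4.37), hmgb1a (-4.37) and hgd (-4.36) had fallen. Aldh1a2 (3.10), fn1b (3.08), junba (2.72), pcna (2.35), mmp9 (1.80) and wnt5b (1.17) rose, and lef1 (0.72) did not pass except with array weights and without control 24 h replicate 3. Msx1b overlapped, from 5.88 to 6.57 on control 0 h and from 5.51 to 6.76 on control 48 h arrays. The mean of the fin regeneration markers did not rise on control arrays. It was 4.91 ± 0.16 at 0 h, 4.83 ± 0.05 at 24 h and 4.84 ± 0.03 at 48 h (SD, n = 3). The control 0 h means of ntrnl2, inhbaa, aldh1a2 and wnt5b and the control 48 h means of and1 and hgd lay in the range of the dimmest probe sets. Ribosome biogenesis genes had 34 higher and 1 lower of 46, or 35 and 1 adjusted over the list alone (mybbp1a 2.17, wdr75 1.88). Hypoxia and glycolysis had 19 higher and 3 lower of 45, or 19 and 4 adjusted over the list alone (pfkpa 2.70, pkma 2.43), and ribosomal proteins had 7 higher and 35 lower of 73, also adjusted over the list alone (rpl34 -1.40, rplp2 -1.22). All 9 list calls were lost with an estimated correlation (adjusted p = 0.728 with an estimated correlation for each of these 3). In total 4531 probe sets passed, 2297 higher and 2234 lower, or 2166 and 2457 after cyclic loess. Poly-A spike-ins were at 7.15 ± 0.38 on the control 0 h and 7.94 ± 0.13 on the control 48 h arrays (SD, n = 3). On the diabetic arrays they were at 6.26 ± 0.32 at 0 h and 7.23 ± 0.33 at 48 h. A labelling batch therefore cannot be told apart from time between 0 h and 48 h.

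Within the diabetic arrays, kif20a (4.49 ± 0.28, SE), tcnbb (2.54), the hypoxia-responsive ndrg1a (2.26), and nccrp1 (2.18) rose by 12 h. Col10a1a (-3.50 ± 0.54), col10a1b (-3.18), enam (-2.96) and irg1l (-2.60) fell, the last not passing without diabetic 0 h replicate 2 (-2.26) or diabetic 12 h replicate 2 (-2.43). No landmark gene passed, with mmp13a at 2.46 ± 0.84, lef1 at -1.50 ± 0.38 and mmp9 at 1.26 ± 0.35. These 3 passed without control 24 h replicate 3, with the same values, and with array weights. Fibrillar collagen and bone matrix genes fell (0 higher, 6 lower of 19; 0 and 7 adjusted over the list alone; spp1 -1.21, col1a2 -1.07), with adjusted p = 0.00256 with an estimated correlation. In total 185 probe sets passed, 128 higher and 57 lower. The count was 82, 94 and 96 without diabetic 0 h replicate 1, 2 and 3, 83 and 106 without diabetic 12 h replicate 1 and 2, 637 without control 24 h replicate 3 and 4170 with array weights. With array weights most were lower (1519 higher, 2651 lower), so the direction of the balance turned.

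By 24 h ifitm5 (6.13 ± 0.28, SE), and2 (5.93), ecrg4a (5.26), pcp4a (4.59), the proteoglycan gene ncana (4.57), enam (4.24), bhmt (4.14) and the lysyl oxidase gene loxa (3.77) had risen on the diabetic arrays. Jac4 (-3.95), ntrnl2 (-3.72), prg4a (-3.67), muc5.2 (-2.44), stmn1b (-2.39), dspa (-2.19), tph1b (-2.03) and saa (-1.99) had fallen. Jac4 did not pass without diabetic 0 h replicates 1 (-3.66) and 2 (-3.95) or diabetic 24 h replicates 1, 2 and 3 (-4.15, -3.87 and -3.84). Ntrnl2 did not pass without diabetic 0 h replicates 1, 2 and 3 (-3.57, -3.66 and -3.94) or diabetic 24 h replicates 1, 2 and 3 (-3.99, -3.83 and -3.34). The diabetic 0 h means of ifitm5 and ncana lay in the range of the dimmest probe sets. Msx1b rose (1.52), whereas mmp13a (0.46), pcna (-0.50), junba (-0.34) and fn1b (-0.58) did not pass. Fin regeneration markers had 12 higher and 1 lower of 57, or 18 and 2 adjusted over the list alone (bmp4 1.94, evx1 1.53; adjusted p = 0.000255 with an estimated correlation). Fibroblast and connective tissue markers had 11 higher and 0 lower of 29, or 17 and 0 adjusted over the list alone (dcn 2.31, tgfbi 2.51; adjusted p = 0.000255 with an estimated correlation). Fibrillar collagen and bone matrix genes had 10 higher and 1 lower of 19, or 12 and 2 adjusted over the list alone (adjusted p = 0.000702 with an estimated correlation). Epidermis and keratin markers fell, with 1 higher and 13 lower of 50, or 1 and 23 adjusted over the list alone (krt4 -1.51, spint1a -0.90; adjusted p = 0.0406 with an estimated correlation). In total 811 probe sets passed, 581 higher and 230 lower. The count was 539 without diabetic 0 h replicate 2, 1434 without control 24 h replicate 3, 1503 when only these groups were fitted and 3587 with array weights, where the balance turned (1472 higher, 2115 lower).

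By 48 h and2 (5.76 ± 0.44, SE), ifitm5 (5.08), ecrg4a (4.91), pcp4a, enam (3.38), twist3 (3.17), bhmt (3.02) and col10a1a (2.95) had risen on the diabetic arrays. Irg1l (-3.06), the desmoplakin gene dspa (-2.86), stmn1b (-2.57), prg4a (-2.50), cd44a (-2.08), musk (-2.01), agr2 (-2.00) and higd1a (-1.85) had fallen. Ifitm5 at 0 h and irg1l at 48 h had means as low as the dimmest probe sets. Fin regeneration markers had 16 higher and 0 lower of 57, or 19 and 1 adjusted over the list alone (msx2b 2.43, evx1 1.61; adjusted p = 0.00101 with an estimated correlation). Epidermis and keratin markers had 0 higher and 17 lower of 50, or 0 and 25 adjusted over the list alone (jupa -0.81, krt91 -0.90; adjusted p = 0.00466 with an estimated correlation). In total 667 probe sets passed, 420 higher and 247 lower. The count was 386 and 397 without diabetic 0 h replicate 2 and 3, 1328 without control 24 h replicate 3 and 2337 with array weights (1173 higher, 1164 lower).

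The responses of the control and diabetic arrays were then compared directly. At 12 h tcnbb (2.49 ± 0.33, SE), nccrp1 (2.29) and s100z (2.18) had a more positive response on the diabetic arrays, and enam (-2.77), cfap298 (-1.92) and spon2b (-1.72) a more negative one. S100z did not pass without diabetic 0 h replicate 2 (2.04) or diabetic 12 h replicates 1 (2.15) and 2 (2.12), nor cfap298 without control 12 h replicate 3 (-1.81). Nccrp1 did not pass without control 0 h replicate 2 (2.06), control 12 h replicates 1 (2.26) and 3 (2.21), diabetic 0 h replicates 1, 2 and 3 (2.28, 2.28 and 2.32) or diabetic 12 h replicates 1 (2.22) and 2 (2.27). Spon2b did not pass after cyclic loess or without control 0 h replicates 2 (-1.58) and 3 (-1.69), control 12 h replicates 1, 2 and 3 (-1.75, -1.64 and -1.78), diabetic 0 h replicates 1, 2 and 3 (-1.68, -1.74 and -1.75) or diabetic 12 h replicates 1 (-1.65) and 2 (-1.68). At 24 h ifitm5 (8.18 ± 0.40), and2 (8.13), and1 (7.17), ecrg4a (6.80), col10a1b (6.60) and bhmt (6.56) had the most positive difference, and jac4 (-8.73 ± 1.42), ntrnl2 (-7.53), inhbaa (-5.42), hsp70.3 (-5.36), krt18a.1 (-5.07) and tuba1b (-4.56) the most negative. At 48 h and1 (8.10 ± 1.16), and2 (7.67), ifitm5 (7.09), col10a1b (7.06), col10a1a (6.81) and ecrg4a (6.68) were at 1 end, and jac4 (-8.13), ntrnl2 (-7.77), inhbaa (-7.26), krt18a.1 (-6.45), hsp70.3 (-5.96) and tpm4a (-5.65) at the other. In the range of the dimmest probe sets lay the control 12 h mean of s100z, the control 0 h and 12 h means of enam, the control 0 h means of ntrnl2, inhbaa and aldh1a2 and the diabetic 0 h mean of ifitm5. So did the control means of and2 at 24 h, and1 at 48 h and ifitm5 at both. The wound and proliferation landmarks fn1b (-4.09), aldh1a2 (-3.43) and junba (-3.10) had a lower response on the diabetic arrays at 48 h and passed. These genes were already higher on the diabetic arrays at 0 h, so the lower response includes that difference. Fn1b ran from 12.93 to 13.15 on diabetic 0 h and from 11.71 to 12.36 on diabetic 48 h arrays. On control arrays it ran from 9.01 to 9.63 and from 12.42 to 12.57. At 48 h itself, diabetic minus control did not pass for fn1b or junba. Pcna (-2.94) passed, but not without control 0 h replicate 3 (-2.81), control 48 h replicate 3 (-2.89), diabetic 0 h replicate 3 (-2.90) or diabetic 48 h replicate 1 (-2.87). Mmp13a (-3.78) passed, but not without control 0 h replicates 1, 2 and 3 (-3.90, -3.69 and -3.76), control 48 h replicates 1 (-3.59) and 2 (-3.82), diabetic 0 h replicates 2 (-3.92) and 3 (-3.44) or diabetic 48 h replicates 2 (-3.61) and 3 (-3.81). Fibroblast and connective tissue markers had a higher response at 24 h (15 higher, 0 lower of 29; 15 and 1 adjusted over the list alone; adjusted p = 0.00278 with an estimated correlation), and ribosome biogenesis genes a lower one at 48 h (1 higher, 34 lower of 46; 1 and 35 adjusted over the list alone; adjusted p = 0.269 with an estimated correlation). Across probe sets the control and diabetic responses had a Pearson r of 0.17 at 12 h, -0.24 at 24 h and -0.07 at 48 h, with no array in common.

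The responses differed for 75 probe sets at 12 h (41 higher, 34 lower), 2557 at 24 h (1214 higher, 1343 lower) and 2958 at 48 h (1471 higher, 1487 lower). At 24 h the share of higher calls, 47.5%, was 57.6% after cyclic loess (1446 higher, 1066 lower), and at 48 h 1696 were higher and 1247 lower after it. Without control 24 h replicate 3 the counts were 317 (138 higher, 179 lower), 4874 and 4150. The count at 24 h was 1633 without control 24 h replicate 1, 1532 without replicate 2 and 775 when only the compared groups were fitted (502 higher, 273 lower). At 12 h it was 49 and 45 without control 12 h replicate 1 and 3, 39 and 34 without diabetic 0 h replicate 1 and 2, 41 and 45 without diabetic 12 h replicate 1 and 2, and 259 when only the compared groups were fitted (119 higher, 140 lower).

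**Figure D4:**
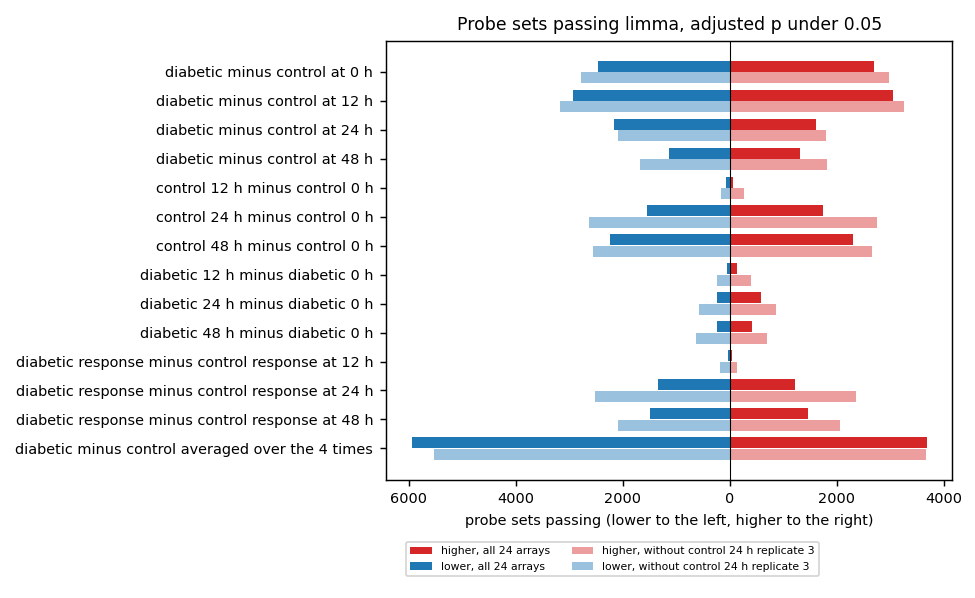
Number of probe sets passing limma at an adjusted p under 0.05 (x axis), higher to the right and lower to the left, for each comparison (rows), with all 24 arrays (dark bars) and without control 24 h replicate 3 (pale bars). Between 0 h and 12 h 131 probe sets passed in control and 185 in diabetic arrays, against 5159 between diabetic and control at 0 h.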

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

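The tests on single arrays, on labels and batches and on dim probe sets and scaling were chosen after the results were seen, whereas the counts over other splits of the arrays were planned. Groups of 3 arrays were not tested for outliers.

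The response to amputation differed between control and diabetic arrays by a test of the difference itself for 75 probe sets at 12 h, 2557 at 24 h and 2958 at 48 h. At 12 h the genes with the most positive differences were tcnbb (2.49), nccrp1 (2.29) and s100z (2.18), and those with the most negative enam (-2.77), cfap298 (-1.92) and spon2b (-1.72). At 24 h they were ifitm5 (8.18), and2 (8.13) and and1 (7.17), and jac4 (-8.73), ntrnl2 (-7.53) and inhbaa (-5.42). At 48 h they were and1 (8.10), and2 (7.67) and ifitm5 (7.09), and jac4 (-8.13), ntrnl2 (-7.77) and inhbaa (-7.26). Jac4, ntrnl2 and inhbaa were already higher on the diabetic arrays at 0 h, so their negative values include that difference. The positive value of and1 at 48 h includes a fall on control arrays. There and1 ran from 8.17 to 9.88 at 0 h and from 2.75 to 3.36 at 48 h. On diabetic arrays it ran from 10.32 to 10.99 and from 12.97 to 13.21. Without control 24 h replicate 3 the counts were 317, 4874 and 4150, without control 24 h replicates 1 and 2 the 24 h count was 1633 and 1532, and leaving out arrays of the 12 h comparison took its count as low as 34, without diabetic 0 h replicate 2.

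Among 100 splits of the arrays, 13 gave as many probe sets as the 75 at 12 h (highest other 4371) and 6 as many as the 2557 at 24 h (highest other 4232). At 48 h 2 splits of 100, the real one included, gave as many as the 2958 (highest other 3207). The splits exchange treatment labels within each time, so they stand for no treatment difference at all rather than for equal responses. Because treatments differed at 0 h, these shares cannot decide about a difference between responses. On average over the times 1 split of 100, the real one, gave 9625 (highest other 183), so a random split of these arrays is an unlikely source of that count. Whether the arrays are independent samples is not known, so chance differences between the groups of fish were not excluded. For the other 10 comparisons there are 10 splits each, too few for a share under 0.05, and 1 split, the real one, reached the count in each. The real count and the highest other were 5159 and 1 for diabetic minus control at 0 h, 5989 and 1 at 12 h, 3777 and 96 at 24 h, and 2442 and 3 at 48 h. For control arrays they were 131 and 10 at 12 h, 3274 and 2575 at 24 h and 4531 and 1 at 48 h, and for diabetic arrays 185 and 1, 811 and 2, and 667 and 1. The 2575 came from a split that exchanges control 24 h replicate 3 with a control 0 h array.

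The array labelled control 24 h replicate 3 stood apart from its group. Degraded RNA is argued against by its GAPDH 3' minus 5' difference of 1.24, below the 1.35 and 1.42 of the other arrays of its group. A mislabelled array or exchanged RNA may account for it: its mean correlation with the control 12 h arrays was 0.992, within the 0.992 to 0.993 among those arrays, against 0.916 with its own group. A separate labelling batch cannot be told apart from this, because its poly-A spike-in level of 6.75 (8.33 and 8.12 in replicates 1 and 2) is near the control 12 h arrays, which a relabelled array would show too. No biological explanation was tested, and a slow response in this sample stays open.

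The arrays labelled diabetic and control differed already at 0 h (5159 calls) and at 12 h, whereas between 0 h and 12 h 131 probe sets passed in control and 185 in diabetic arrays, although 4170 with array weights and 637 without control 24 h replicate 3 in the latter. Labels of time and treatment exchanged between arrays could give this. Over probe sets, the difference at 0 h had r = 0.75 with control 48 h minus control 12 h, which shares no array with it. Both differences subtract control arrays that were nearly alike (median correlation 0.983 between control 0 h and 12 h), which can raise r by itself. The value therefore cannot decide whether arrays labelled diabetic 0 h held a regenerating fin. A labelling batch cannot be told apart from the groups at 0 h, where poly-A spike-ins differed by -0.89 (exact permutation p = 0.10). At 12 h, with 5989 calls, they differed by -0.15 (exact permutation p = 0.40), which argues weakly, with 3 arrays per group, against a batch that moves the spike-ins as the whole cause. A batch that leaves the spike-ins alone stays open. Array medians at 12 h did not overlap, at 3.85 to 3.87 on control and 3.90 to 3.94 on diabetic arrays. A wound present before amputation in the diabetic fish was not decided by the inflammatory list, with a median of 0.26 over members that went both ways (SD 1.79). An effect of diabetes itself on the unwounded fin also stays open, and no values were recomputed under other labels.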

How the results depend on the processing

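Leaving out control 24 h replicate 3 from comparisons that do not use it, leaving out arrays for the gene lists, and the lymphocyte list without polr1g, were chosen after seeing the data; the other alternatives were planned. With an intensity trend and robust prior, without the dimmest probe sets, after cyclic loess and with the replicate number as a block, all 14 counts stayed within 1.5 times the reported ones (5174 for diabetic minus control at 0 h with the block). Replicates with the same number correlated best with each other in 3 of 3 pairs for diabetic minus control at 12 h (0.14, 0.16 and 0.05), control 24 h (0.15, 0.13 and 0.07) and control 48 h (0.12, 0.10 and 0.09), so a pairing is not excluded there, although no comparison had all 3 above 0.1; with the block these counts were 5993, 3296 and 4525. Outside this bound, leaving out 1 array gave 2088 to 3896 for diabetic minus control at 24 h, 67 to 430 for control 12 h, 1035 to 5373 for control 24 h, 82 to 637 for diabetic 12 h, 539 to 1434 for diabetic 24 h and 386 to 1328 for diabetic 48 h. For the differences between responses it gave 34 to 317 at 12 h and 1532 to 4874 at 24 h. Each highest value was without control 24 h replicate 3, whose distance from its group widens the shared error. With 1 probe set per gene, where fewer features are tested, the counts were 3870, 1980 and 1567 for diabetic minus control at 12, 24 and 48 h, 72 and 3016 for control 12 h and 48 h, 484 and 421 for diabetic 24 h and 48 h, 48 for the difference between responses at 12 h and 5427 on average. Median centring gave 6198 for diabetic minus control at 24 h. Fitting only the compared groups gave 832 there, 31 and 2 for control 12 h and 24 h, 1503 for diabetic 24 h, and 259 and 775 for the differences between responses at 12 h and 24 h. Array weights gave 4158 for diabetic minus control at 48 h, 210 for control 12 h, 4170, 3587 and 2337 for diabetic 12, 24 and 48 h, and 461 and 4932 for the differences between responses at 12 h and 24 h. For these the cause was not tested. Of 185 list calls, 27 held and 158 were lost with an estimated correlation, 147 held with fry and 149 after cyclic loess, where 35 were lost and skeletal muscle markers on average went from -0.07 to 0.01. Whether signal near background limits the dimmest probe sets was not tested.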

Other observations

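The tests on dim probe sets and on scaling were chosen after the result was seen.

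On average over the times, complement and acute phase genes were lower on the diabetic arrays (0 higher and 18 lower of 27, also adjusted over the list alone), as were nerve and glial markers (6 higher and 16 lower of 33, or 6 and 17 adjusted over the list alone), with adjusted p = 0.398 with an estimated correlation for each. Of the 18 lower complement and acute phase genes 11 were among the dimmest probe sets, and of the 16 lower nerve and glial markers 9. In that part of the probe sets 91.9% of all calls were lower, so a fall of these lists was not shown apart from it. Mitosis genes were higher at 24 h, with 17 higher and 2 lower of 40, or 18 and 2 adjusted over the list alone, and adjusted p = 0.285 with an estimated correlation.

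More probe sets were lower than higher on average over the times, 61.8% of 9625. Among calls of at least 2-fold the balance turned, with 824 higher and 555 lower. The excess of lower calls lay in the dimmest part of the probe sets, where 2490 of 2708 calls (91.9%) were lower. In the brighter part 49.9% were lower, so no excess was seen there. The background level of dim probe sets may account for this, and it was not shown to be the cause. Array scaling cannot be told apart from a real excess: 51.0% of calls were lower after cyclic loess, which tends to balance each pair of arrays, whereas median centring left 3348 higher and 8001 lower. No biological explanation was tested.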
